A study of Homo sapiens with 8 samples.

How the data were processed

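Poly(A) RNA of QBC-939 cells was sequenced as paired-end reads in 8 libraries, 4 labelled SMAD4 knockdown and 4 labelled control, per the labels. The labels' extraction text speaks of adipose tissue, which does not match the cell line named elsewhere in the same labels. The authors deposited a single table of genes in which each library has a column of counts and a column of FPKM, per the file headers. The counts were deposited as whole numbers that were not normalized. The deposited FPKM values are counts scaled by gene length and library total. Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 are named, per the submitters' processing notes, without their roles, and the counting tool, the annotation and the use of strand were not given in the sources used here. Without stated strand use, reads of overlapping genes on opposite strands cannot be told apart. The notes name the build hg19, but the coordinates in the table are those of GRCh38: 94.7% of the gene identifiers were found in GENCODE release 29, and 96.3% of those had a start within 1000 bp of the GENCODE start. Coordinates are given as in the table.

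Libraries were assigned to groups and replicates from their labels. Total counts ran from 63450619 to 70467274 per library. A count of 3 in a library corresponded to 0.0462 CPM in the libraries labelled knockdown and 0.0454 CPM in the control libraries. Reads carried no molecular identifiers, so these floors cover counting error only. No library pair agreed within sampling noise: the median chi-square per gene within a group was 3.54 or more, against 0.455 for counting noise alone, so all 8 libraries were kept as separate.

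The design, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The design foresaw limma on log2(FPKM + 0.5) unless the table also held counts, in which case the edgeR quasi-likelihood test would be the main test. The table held counts, so edgeR 4.0.16 in R 4.3.3 was used, with TMM scaling, the group as the only term and genes kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 21151 of 37089 genes. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05, two-sided. Levels are counts scaled by TMM to a common library size (CPM) with the SD over 4 libraries. Log2 fold changes are the libraries labelled knockdown minus control, with standard errors from the quasi-likelihood F statistic. Single genes of interest were also tested with exact permutation tests on log2 CPM.

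The named genes were SMAD4 and STING1, the 15 largest rises and 15 largest falls among protein-coding genes past the threshold with a mean FPKM of at least 1 in the higher group and no overlap between groups, up to 4 members of each list with the smallest adjusted p, SMAD2, SMAD3, SMAD7, TGFBR1, TGFBR2, CGAS, TBK1 and IRF3 in every case, the 5 genes of smallest p in each direction, and genes that overlap or copy one of these. A selection of these is given. Members named outside the rule were chosen after their values were seen. They are TGFB1, COL12A1, IRF7, IFITM2, PARP9, MX1, OAS1, IFI6 and VEGFA, and the genes named only in the closing observations. The 26 gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with the correlation estimated, and with fry. Gene Ontology terms of 10 to 500 genes came from the deposited table and were tested with a one-sided hypergeometric test against the 15026 tested genes that carry a term.

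The tests were run on simulated counts with the real means, library sizes and dispersions of 21151 genes, 200 of them changed, for the comparison of the libraries labelled SMAD4 knockdown with control. The edgeR test recovered 6 of 50 genes changed 1.5-fold, 20 of 50 changed 2-fold, 35 of 50 changed 4-fold and 41 of 50 changed 8-fold, with 6 false calls. A recovery of 90% at 8-fold had been required at first and was not met at 82%, so that requirement was dropped and the recoveries are given as they came out. The fitted sizes were close to those planted, with a median of 2.94 for a planted log2 change of 3. Among planted genes at 5 CPM or more, 25 of 25 changed 8-fold, 28 of 28 changed 4-fold and 20 of 30 changed 2-fold were recovered, so the misses at 4-fold and above were genes of low count. A planted list of 25 genes changed 1.5-fold was recovered by camera, and 0 of 25 unchanged lists were called. The simulated genes were drawn independently of each other, so this says nothing of false calls in lists whose members are correlated.

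Alternatives covered scaling (DESeq2 size factors, total counts, TPM, median centring and quantile normalization), filters, pseudocounts of 0.1 and 1, the variance model, limma on FPKM, DESeq2 1.42.0, leaving out each library, leaving out mitochondrially encoded genes, and the replicate number as a block. Added after seeing the data were the separate report of values without control replicate 4, edgeR with total-count scaling, with robust dispersion and with an FPKM filter of 1, the Gene Ontology test without control replicate 4, and a correction for gene length and GC content. Figures were drawn with matplotlib 3.10.9.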

Results

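Poly(A)-selected RNA of QBC-939 cells, a line described in the labels as bile duct cancer (cholangiocarcinoma), was measured by paired-end RNA sequencing in 8 libraries. The labels assigned 4 libraries to a SMAD4 knockdown group and 4 to a control group. SMAD4 is the shared partner of the receptor-activated SMAD proteins in TGF-beta and BMP signalling. The question named by the series was whether SMAD4 acts on cholangiocarcinoma cells through the expression of STING1, the adaptor that relays cytosolic DNA sensing by cGAS. The deposited table held counts and FPKM values for 37089 genes. Total counts ran from 63505753 to 64523827 in the libraries labelled knockdown and from 63450619 to 70467274 in the control libraries. Nothing in the labels said whether the replicates were separate cultures, so the p-values below measure the spread between these libraries, which may be technical.

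SMAD4, the named target, was higher in the libraries labelled SMAD4 knockdown than in those labelled control, against the labels. Its level was 70.2 ± 1.72 CPM (SD, n = 4) in the libraries labelled knockdown and 25.7 ± 1.37 CPM (SD, n = 4) in the control libraries, a 2.73-fold difference. The log2 fold change was 1.45 with a standard error of 0.0802 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.073e-05). All 4 libraries labelled knockdown lay above all 4 control libraries, with counts of 4436 to 4682 against 1393 to 1935. A two-sided exact permutation test gave p = 0.02857, the smallest value that 70 assignments of the 8 libraries allow. SMAD4 (ENSG00000141646) lies on the plus strand of chromosome 18 from 51028394 to 51085045. Every direction below is that of the libraries labelled knockdown against those labelled control, and the label of the knockdown is not borne out by the SMAD4 level.

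STING1 did not pass the threshold in the edgeR test of all libraries. Its level was 5.80 ± 0.210 CPM (SD, n = 4) in the libraries labelled knockdown and 4.58 ± 0.347 CPM (SD, n = 4) in the control libraries. The log2 fold change was 0.34 with a standard error of 0.13 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.08542). It passed with limma on TPM, at 0.43 (adjusted p = 0.0432), and with limma on FPKM without a variance trend, at 0.26 (adjusted p = 0.0412), within a range of 0.0412 to 0.495 over the alternatives. TPM moved genes upward in general, with a median over all genes of 0.159 against 0.0635 with limma on log2(FPKM + 0.5), so that pass is not particular to STING1. The 4 values of each group did not overlap, and the two-sided exact permutation test of this single gene gave p = 0.02857, again the smallest possible. STING1 (ENSG00000184584) lies on the minus strand of chromosome 5 from 139475533 to 139482758. CGAS, the DNA sensor upstream of STING1, had 0, 7, 0 and 4 counts in the libraries labelled knockdown and 12, 16, 4 and 4 in the control libraries, too few to enter the test.

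**Figure D1:**
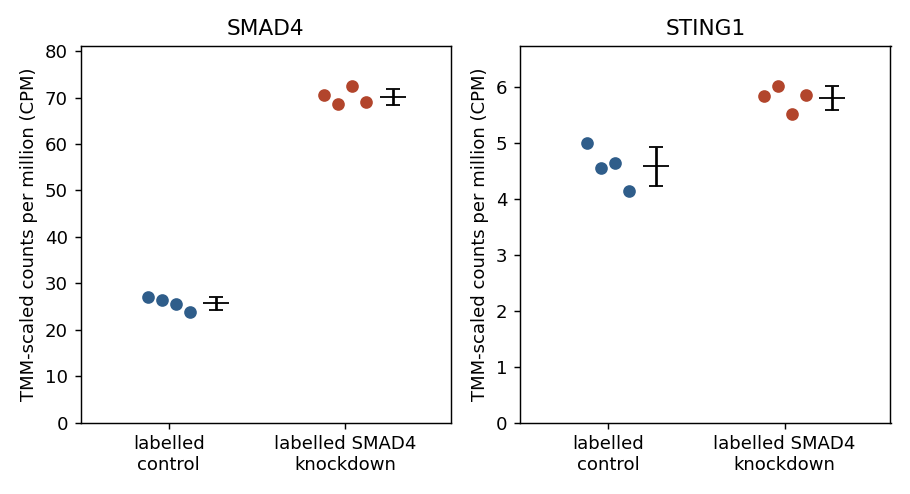
Normalised expression of SMAD4 and STING1 in each library, in TMM-scaled CPM, for the groups labelled control and SMAD4 knockdown, where points are libraries and the horizontal mark with bars is the mean ± SD of 4. SMAD4 was 68.6 to 72.4 CPM in the libraries labelled knockdown and 23.9 to 27 CPM in the control libraries.

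Genes of the antiviral interferon response were among the largest rises in the libraries labelled knockdown. IFIT2, IFIT3 and IFIT1, interferon-induced RNA-binding proteins that restrict viral translation, rose by log2 fold changes of 7.42, 6.92 and 5.63. IFIT2 went from 1.44 ± 0.275 to 248 ± 3.75 CPM and IFIT1 from 8.34 ± 1.08 to 412 ± 15.4 CPM (SD, n = 4 each). OASL rose by 6.29, and IFNB1, which encodes interferon beta, by 6.23, from 0.0417 ± 0.0651 to 3.04 ± 0.289 CPM (SD, n = 4 each). The control level of IFNB1 lay under the 3-count floor of 0.0454 CPM, and its log2 fold change was 8.03 without control replicate 4, so its size is uncertain. The cytosolic RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5) rose by 4.13 and 3.74, DDX58 from 4.31 ± 0.481 to 75.3 ± 1.84 CPM (SD, n = 4 each). Of 38 interferon-stimulated genes tested, 17 rose, 3 fell and 18 were not called, with 18 higher and 3 lower when adjusted over the list alone. The list shifted upward as a whole (camera, adjusted p = 6.55e-34, and adjusted p = 0.00313 with an estimated correlation). The 3 that fell were IRF7, IFITM2 and PARP9, with log2 fold changes of -2.47, -1.0 and -1.06. Not every classical member moved: MX1 had a log2 fold change of -0.90, OAS1 -0.72 and IFI6 -0.52, none of them called. Those 3 were singled out after their values were seen. IFIT1, IFIT2 and IFIT3 lie within the annotated span of LIPA on chromosome 10, which itself was at 89.5 ± 5.42 and 94.7 ± 5.27 CPM (SD, n = 4 each).

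Cytokine and chemokine genes moved with them. CCL5, a T cell attractant, rose from 2.61 ± 1.18 to 299 ± 9.87 CPM (SD, n = 4 each), a log2 fold change of 6.84. CXCL10 and CXCL11, ligands of CXCR3, rose by 6.06 and 4.97. Their control levels were only 0.253 and 0.0836 CPM, and over the alternatives the values fell as low as 3.65 and 1.25. TNFAIP3, an inhibitor of NF-kappaB signalling that is itself induced by it, rose by 1.94. CXCL16 fell by 3.8 on the log2 scale, from 13.9 ± 0.968 to 0.996 ± 0.226 CPM (SD, n = 4 each). It overlaps MED11, and without stated strand use their reads cannot be told apart. Of 26 NF-kappaB targets, cytokines and chemokines tested, 11 rose, 1 fell and 14 were not called, and the numbers were 11 and 1 when adjusted over the list alone (camera, adjusted p = 1.26e-07, and adjusted p = 0.00656 with an estimated correlation), while 14 rose and 2 fell without control replicate 4. VCAM1, a vascular adhesion molecule outside that list, rose by 6.01, or 6.90 without control replicate 4. Its control level was only 0.160 CPM, and over the alternatives its value fell as low as 1.36. MYD88, the adaptor of Toll-like receptor signalling, fell by 3.67 on the log2 scale, from 5.77 ± 1.93 to 0.453 ± 0.129 CPM (SD, n = 4 each).

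The cGAS-STING pathway components did not move one way. Of 20 tested, 4 rose, 3 fell and 13 were not called, and adjusted over the list alone the numbers were again 4 and 3 (camera, adjusted p = 0.637). ENPP1, which degrades the STING ligand cGAMP, rose by 0.72. TBK1 and IRF3, the kinase and transcription factor downstream of STING1, had log2 fold changes of -0.18 and -0.28 and were not called. IRF3 overlaps BCL2L12, so its reads are uncertain, and its value ran from -0.42 to -0.09 leaving out 1 library. Among 17 genes of MHC class I antigen presentation, 4 rose and none fell, also when adjusted over the list alone (camera, adjusted p = 0.135). TAP2, B2M and CALR were among them, with log2 fold changes of 1.14, 0.75 and 0.47. TAP2 overlaps another annotated protein-coding gene, so its reads are uncertain. Without control replicate 4, 5 pathway components rose and 5 fell, and the MHC class I list passed (camera, adjusted p = 0.0102). With all libraries that list also passed with no filter on low counts, with quantile normalization and with DESeq2 (adjusted p = 0.0276, 0.0318 and 0.0344), within a range of 0.0102 to 0.334 over the alternatives. These calls were at the preset correlation, and with an estimated one the list gave adjusted p = 0.331 (camera, all libraries). B2M was 291 ± 19.2 CPM in the libraries labelled knockdown and 173 ± 49.6 CPM in the control libraries (SD, n = 4 each).

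**Figure D2:**
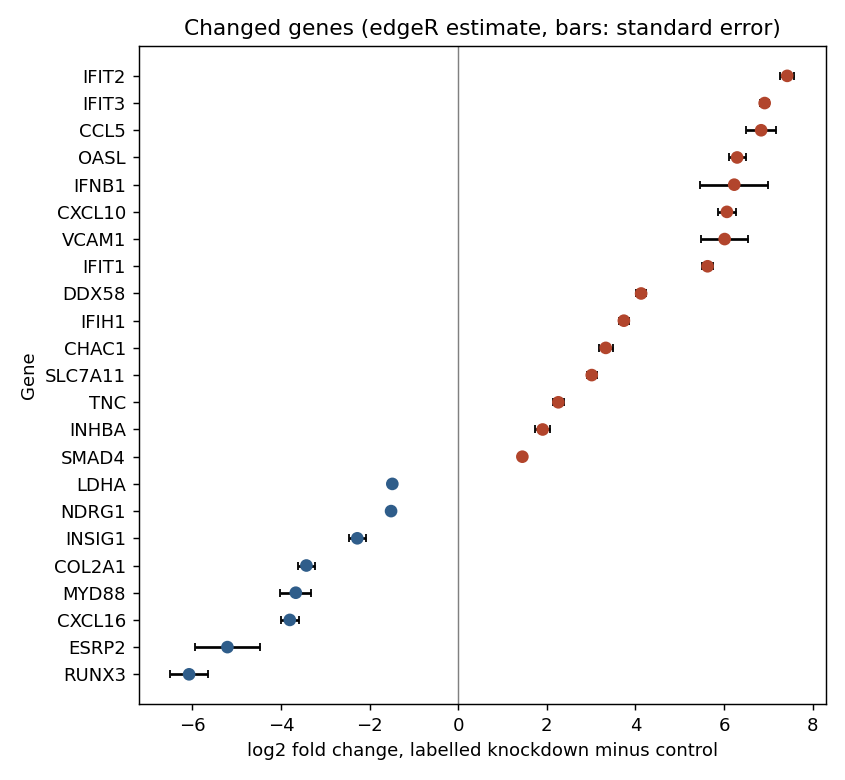
Log2 fold changes, libraries labelled SMAD4 knockdown minus control, of 23 genes named in the text that passed the threshold, with points as edgeR estimates and bars as their standard errors (n = 4 libraries per group). The values run from 7.42 for IFIT2 to -6.07 for RUNX3.

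Targets of ATF4 and the unfolded protein response rose together. CHAC1, which degrades glutathione, rose from 2.47 ± 0.374 to 24.8 ± 2.08 CPM, and SLC7A11, the cystine importer, from 10.5 ± 1.23 to 84.5 ± 3.97 CPM (SD, n = 4 each), log2 fold changes of 3.33 and 3.01. PSAT1, a serine synthesis enzyme, rose by 1.16 and VLDLR by 0.89. Of 23 tested, 17 rose, none fell and 6 were not called, with 17 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 8.98e-17, and adjusted p = 0.0431 with an estimated correlation). Without control replicate 4, a library that stood apart from the other controls, 22 rose. In that library the list lay higher than in the other controls by a median log2 difference of 0.40.

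Hypoxia and glycolysis genes were lower in the libraries labelled knockdown. LDHA, which converts pyruvate to lactate, fell from 1473 ± 61.7 to 525 ± 20.8 CPM (SD, n = 4 each), a log2 fold change of -1.49. NDRG1 had a log2 fold change of -1.52, and the glycolytic enzymes PGAM1 and ENO1 -1.3 and -1.09. Of 25 tested, 1 rose, 14 fell and 10 were not called, and 1 and 15 when adjusted over the list alone (camera, adjusted p = 1.68e-11, and adjusted p = 0.00313 with an estimated correlation). The gene that rose was VEGFA, with a log2 fold change of 0.60. Cholesterol biosynthesis genes fell in 9 of 23 members and rose in none, also when adjusted over the list alone (camera, adjusted p = 0.000258, but adjusted p = 0.238 with an estimated correlation). INSIG1, a sterol-regulated brake on that pathway, had a log2 fold change of -2.28, HMGCS1 -1.27 and FDFT1 -0.94. Control replicate 4 lay above the other controls for this list by a median log2 difference of 0.37, and without it 3 members rose and 14 fell.

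Mitotic genes were lower. AURKA, AURKB, CCNA2 and BUB1 had log2 fold changes of -0.93, -0.84, -0.79 and -0.66, BUB1 falling from 166 ± 6.49 to 105 ± 3.19 CPM (SD, n = 4 each). CCNA2 overlaps EXOSC9, so its reads are uncertain. Of 28 G2/M genes, 1 rose, 14 fell and 13 were not called, and 1 and 16 when adjusted over the list alone (camera, adjusted p = 8.25e-05, and adjusted p = 0.047 with an estimated correlation). Of 28 G1/S and DNA replication genes, 3 rose and 5 fell, also when adjusted over the list alone (camera, adjusted p = 0.295), among them CCNE1 and RRM2 with log2 fold changes of -0.90 and -0.51. Leaving out control replicate 4, 6 of these rose and 11 fell. Of 20 p53 targets, 9 rose and 2 fell, and 11 and 3 when adjusted over the list alone (camera, adjusted p = 0.0276, but adjusted p = 0.225 with an estimated correlation), while 13 rose and 4 fell without control replicate 4. The p53 call was lost without control replicate 2 (camera, adjusted p = 0.0511) and in 3 settings with all libraries, the range over the alternatives being 0.00175 to 0.0776. FAS rose by 0.97, XPC by 0.66 and MDM2 by 0.50. FAS overlaps ACTA2 and STAMBPL1, and MDM2 overlaps CPM, so their reads are uncertain.

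Genes of the SMAD pathway itself were higher in 11 of the 12 called components, in the same libraries in which SMAD4 was higher against its label. TGFB1, named after its value was seen, had a log2 fold change of -0.76. INHBA, which encodes an activin subunit, rose by 1.91, SMAD9, a BMP-responsive SMAD, by 1.44 and BMPR2 by 1.15. The inhibitory SMAD6 and SMAD7 each rose by 0.82, and SMAD7 was 20.3 ± 1.31 CPM against 11.5 ± 1.98 CPM (SD, n = 4 each). TGFBR2 rose by 0.88, while TGFBR1, SMAD2 and SMAD3 had log2 fold changes of 0.19, 0.20 and 0.37 and were not called. Without control replicate 4 these 3 passed, at 0.20, 0.23 and 0.24 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0409, 0.00705 and 0.00508). With all libraries, TGFBR1 passed with an FPKM filter of 5 and with TPM, SMAD2 with total-count scaling and SMAD3 with TPM (edgeR or limma, adjusted p = 0.0483, 0.0203, 0.0437 and 0.0437), and the highest values of the alternatives were 0.338 for TGFBR1, 0.785 for SMAD2 and 0.17 for SMAD3. With TPM genes moved upward in general, by a median of 0.159. Of 30 pathway components, 11 rose, 1 fell and 18 were not called, and 12 and 1 when adjusted over the list alone (camera, adjusted p = 0.000254, but adjusted p = 0.238 with an estimated correlation). Of 32 TGF-beta and BMP target genes, 10 rose, 1 fell and 21 were not called, and 10 and 2 when adjusted over the list alone (camera, adjusted p = 0.0276, but adjusted p = 0.53 with an estimated correlation). The call on the targets was lost without replicate 1 labelled knockdown, control replicate 1 or control replicate 2 (camera, adjusted p = 0.0554, 0.0987 and 0.0511), the range over the alternatives being 0.00338 to 0.0987. LTBP2, a matrix protein, rose by 1.43, the transcription factor SNAI2 by 1.10 and BHLHE40 by 0.49. Control replicate 4 lay below the other controls for the pathway components, by a median log2 difference of -0.29, and above them for the targets, by 0.23. Without it, 18 components rose and 2 fell, and 14 targets rose and 2 fell.

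Collagens and other matrix genes rose in 7 of 26 members and fell in 1, also when adjusted over the list alone (camera, adjusted p = 0.000464, but adjusted p = 0.467 with an estimated correlation). TNC, which encodes tenascin-C, rose from 25.2 ± 3.75 to 121 ± 9.40 CPM (SD, n = 4 each), a log2 fold change of 2.26, and COL3A1 and COL5A1 rose by 1.69 and 1.36. The member that fell was COL12A1, named after its value was seen, with a log2 fold change of -0.80. COL2A1, the cartilage collagen, which is outside that list, fell by 3.43 on the log2 scale. This list lay lower in control replicate 4 than in the other controls, by a median log2 difference of -0.49, and without that library 12 members rose and 2 fell. Of 22 mesenchymal genes, 5 rose and 2 fell, and 7 and 3 when adjusted over the list alone (camera, adjusted p = 0.879), while 7 rose and 4 fell without control replicate 4. This list passed with an FPKM filter of 5 (median 0.59 against 0.15, camera, adjusted p = 0.0339, with 0.95 the highest of the alternatives). With the main filter and an estimated correlation the mesenchymal list gave adjusted p = 0.921 (camera). VIM, a mesenchymal intermediate filament, rose by 0.89, whereas CDH2 and PRRX1 had log2 fold changes of -1.33 and -1.98. Of 23 epithelial junction and keratin genes, 2 rose and 3 fell, also when adjusted over the list alone (camera, adjusted p = 0.717). ESRP2, an epithelial splicing regulator, fell from 11.9 ± 3.47 to 0.320 ± 0.286 CPM (SD, n = 4 each), MARVELD2 had a log2 fold change of -1.99 and JUP rose by 0.56. The log2 fold change of ESRP2 ran from -5.92 to -1.54 over the alternatives, so its size is uncertain. The epithelial list had a median log2 difference of -0.47 in control replicate 4 from the other controls, and its median, 0.03, and mean, -0.15, differ in sign, the test following the mean.

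**Figure D3:**
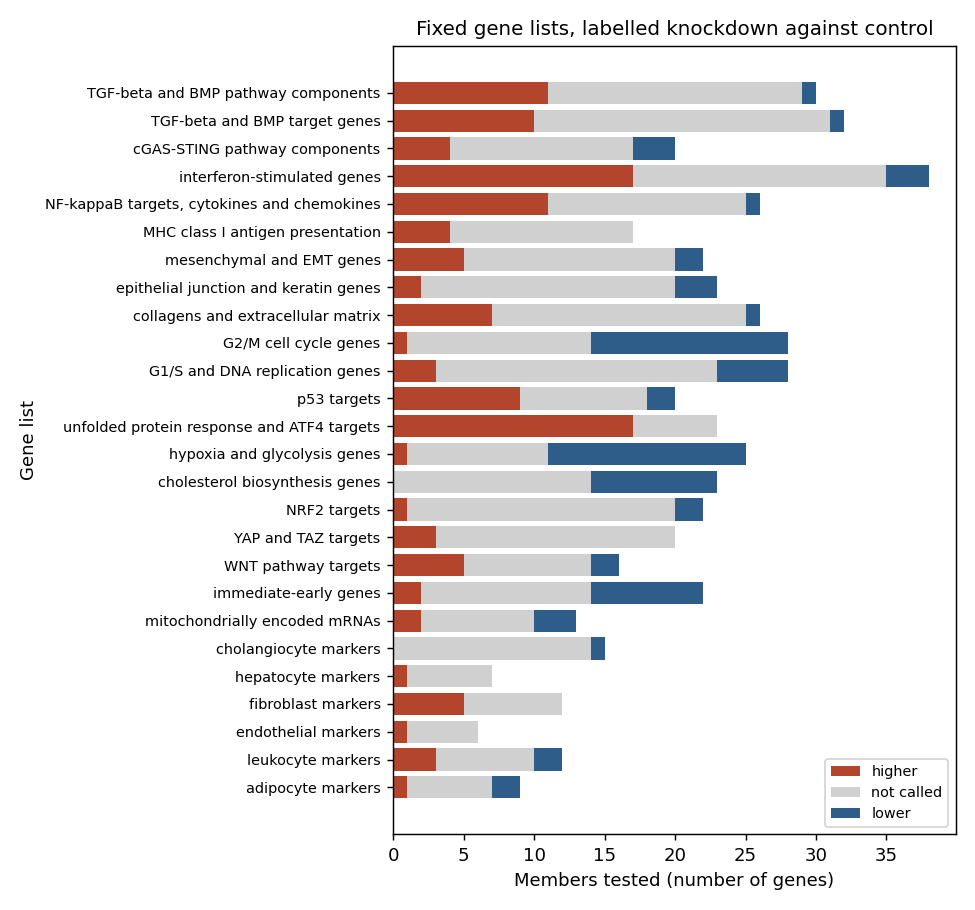
Members of the 26 gene lists by outcome in the libraries labelled SMAD4 knockdown against control, each bar being the number of members tested, split into genes higher, not called and lower. The interferon list holds 17 higher and 3 lower of 38, and the hypoxia and glycolysis list 1 higher and 14 lower of 25.

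Of 22 immediate-early genes, 2 rose and 8 fell, and 2 and 11 when adjusted over the list alone (camera, adjusted p = 0.0632). EGR1 rose by 1.17, while FOSL1 and DUSP5 had log2 fold changes of -1.6 and -1.39. With an estimated correlation the immediate-early list gave adjusted p = 0.538 (camera, all libraries). This list passed without replicate 1 labelled knockdown (camera, adjusted p = 0.0443) and without control replicate 1 (adjusted p = 0.0263), and with all libraries under DESeq2 (adjusted p = 0.00912) and with no filter on low counts (adjusted p = 0.0191), where the highest value of the alternatives was 0.375. NRF2 targets gave 1 higher and 2 lower of 22 (camera, adjusted p = 0.879), YAP and TAZ targets 3 higher and 0 lower of 20 (adjusted p = 0.384) and WNT pathway targets 5 higher and 2 lower of 16 (adjusted p = 0.244), each with the same numbers when adjusted over the list alone. Leaving out control replicate 4, NRF2 targets gave 5 higher and 5 lower, and YAP and TAZ targets 6 higher and 2 lower. Mitochondrially encoded mRNAs moved apart from each other: of 13, MT-ND1 and MT-ND2 rose by 0.99 and 0.95, 3 fell and 8 were not called (camera, adjusted p = 0.16), and 2 rose and 4 fell when adjusted over the list alone. MT-ND6 and MT-CO2 had log2 fold changes of -1.48 and -1.11. With an estimated correlation the list of mitochondrially encoded mRNAs gave adjusted p = 0.663 (camera, all libraries). Mitochondrially encoded genes took 3.72% ± 0.0601 of counts in the libraries labelled knockdown and 4.41% ± 0.970 in the control libraries (SD, n = 4 each), with 3.0% in control replicate 4. Without that library 3 of these mRNAs rose and 6 fell, and the list passed (camera, adjusted p = 0.000138), as it did with all libraries under DESeq2 (adjusted p = 0.00921), where the highest value of the alternatives was 0.945.

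Cholangiocyte markers gave 0 higher and 1 lower of 15, also when adjusted over the list alone (camera, adjusted p = 0.879). Their levels were low for several members: KRT7 was at 0.416 ± 0.297 and 0.103 ± 0.0730 CPM, and EPCAM at 1.06 ± 0.379 and 2.42 ± 1.34 CPM, in the libraries labelled knockdown and control (SD, n = 4 each), and neither was called. EPCAM passed without control replicate 2, at -1.4 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0377), and with all libraries under DESeq2, at -1.2 (adjusted p = 0.0205), the highest value of the alternatives being 0.145. Without control replicate 4 the cholangiocyte markers gave 3 higher and 1 lower. Over the 17 cholangiocyte markers with counts the median level was 1 CPM. The most abundant was SLC4A2, which overlaps CDK5, at 168 CPM in the libraries labelled knockdown and 134 CPM in the control libraries. Whether the cells are of bile duct origin was not tested. Fibroblast markers rose in 5 of 12 members and fell in none, also when adjusted over the list alone (camera, adjusted p = 0.00484, but adjusted p = 0.225 with an estimated correlation). The call was lost in 8 limma settings, the range over the alternatives being 0.000116 to 0.159. They included COL3A1, FBLN1 and LUM, with log2 fold changes of 1.69, 0.77 and 1.35, and FBLN1 was already at 82.0 ± 4.75 CPM in the control libraries (SD, n = 4). Hepatocyte markers gave 1 higher and 0 lower of 7 (adjusted p = 0.377), or 2 and 0 without control replicate 4, endothelial markers 1 and 0 of 6 (adjusted p = 0.398), leukocyte markers 3 and 2 of 12 (adjusted p = 0.717) and adipocyte markers 1 and 2 of 9 (adjusted p = 0.717). Adjusted over the list alone, only the leukocyte numbers differed among these 4 lists, with 3 higher and 3 lower. LCP1, an actin-bundling protein of leukocytes, rose by 2.84, and the lipases LPL and LIPE had log2 fold changes of 2.20 and -2.92.

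Other genes with the largest changes belonged to no single list. RUNX3, a transcription factor downstream of TGF-beta signalling, fell from 16 ± 1.86 to 0.235 ± 0.178 CPM (SD, n = 4 each), and MFAP2, a microfibril protein, from 14.6 ± 4.49 to 0.235 ± 0.0824 CPM (SD, n = 4 each), log2 fold changes of -6.07 and -5.94. The neuronal genes STMN2 and NEFM had log2 fold changes of -5.0 and -2.76, and GPR50, SPINT2, RND2, CA8 and TLE4 -4.76, -3.60, -3.39, -2.22 and -2.10. NEFM was at 631 ± 55.2 CPM in the control libraries and 93.4 ± 8.41 CPM in the libraries labelled knockdown (SD, n = 4 each). The heat-shock genes HSPA1A and HSPA1B had log2 fold changes of -3.32 and -3.34. They are near-identical copies whose reads cannot be assigned with certainty, and SPINT2 overlaps PPP1R14A. Among the rises were ASB11 at 7.16, JAKMIP2 at 5.79 and SAGE1, a cancer-testis antigen, at 5.73. Their control levels were only 0.123, 0.363 and 0.111 CPM. Over the alternatives the values fell as low as 2.64, 1.59 and 1.52, so these sizes are uncertain. The same holds for the falls of RUNX3, MFAP2 and STMN2, whose log2 fold changes were as small in size as -1.94, -2.44 and -1.23 over the alternatives.

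Over all 21151 genes tested, 2912 were higher and 2698 lower in the libraries labelled knockdown, which is 26.5% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes numbered 1051 higher and 989 lower. The groups did not overlap in 7652 of the 21151 tested genes, where chance gives 2.86% of genes if the libraries are independent. They did not overlap in 5404 of the 5610 called genes, which were already selected for a difference between the groups. Among 2362 Gene Ontology terms, 41 were over-represented among the genes that fell, led by the mitochondrial inner membrane with 121 of 421 genes (one-sided hypergeometric test, adjusted p = 2.69e-11). The proteasome complex, with 21 of 52 genes, and structural constituents of chromatin, with 20 of 50, were among them. The mitochondrial inner membrane and proteasome genes lay higher in control replicate 4 than in the other controls, by median log2 differences of 0.61 and 0.58. Without that library the median log2 fold change of the mitochondrial term went from -0.37 to -0.19, with 68 genes higher and 181 lower in place of 24 and 121, and the proteasome had 3 genes higher and 32 lower in place of 1 and 21. No term passed for the genes that rose (lowest adjusted p = 0.0721, with 136 terms at an unadjusted p under 0.05), although 15 did when only rises of at least 2-fold were taken, led by the extracellular matrix (adjusted p = 0.000145), and 21 with all genes tested as the background. Without control replicate 4, 6 terms passed for the genes that rose and 72 for those that fell.

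Control replicate 4 differed at least 2-fold from the mean of the other control libraries in 5111 genes, against 1808 to 2247 for the other controls. The references differ, since the means for the other controls held control replicate 4. Among genes of at least 8 CPM the number was 1519, against 19 to 159 for control replicates 1 to 3 compared among themselves. Ribosomal protein genes took 10.0% of its counts and 5.64% to 6.10% in the other controls. Without it, 4634 genes were higher and 4321 lower, and 5530 of the 5610 genes called with all libraries were called in the same direction. With values rescaled to TPM and tested with limma, 3107 genes were higher and 1538 lower, 66.9% higher against 56.2% with limma on log2(FPKM + 0.5) of the same 13285 genes, and the median of all genes stood 0.16 above 0 on the log2 scale.

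**Figure D4:**
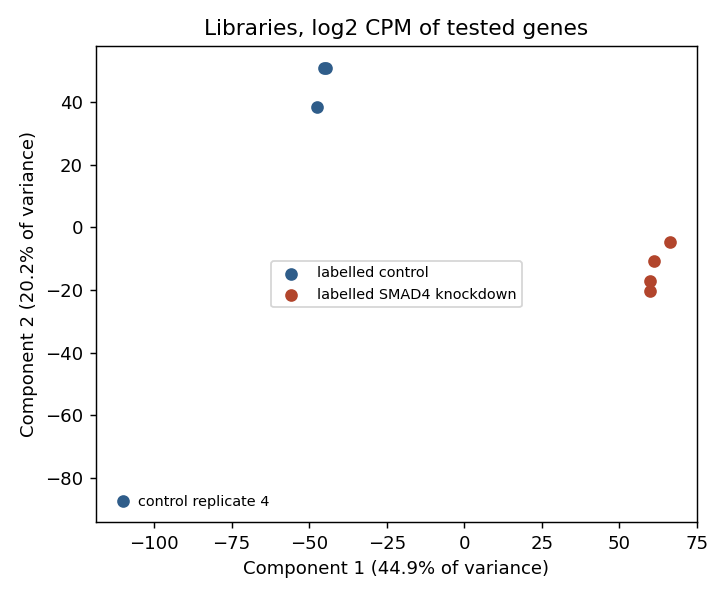
Principal components of the log2 CPM values of the tested genes, 1 point per library, coloured by the labelled group, where component 1 held 44.9% and component 2 20.2% of the variance and the points of control replicates 1 and 2 coincide. The 4 libraries labelled knockdown lie together at 59.7 to 66.3 on component 1, and control replicate 4 lies at -110 on component 1 and -87.3 on component 2, away from the other controls.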

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

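The tests of exchanged labels, chromosome 18 copies and overlapping reads, and, for the genes at least 8-fold apart and under 1 CPM in the lower group, those of other cell types and depth, were chosen only after the result was seen. The others were set beforehand.

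SMAD4 was 2.73-fold higher in the libraries labelled SMAD4 knockdown, against the label. More copies of the whole region within 5 Mb are argued against by its 35 protein-coding genes. Their median log2 fold change was 0.139 (95% bootstrap interval -0.0893 to 0.332) against 1.45 for SMAD4, with 10 called higher and 3 lower. The nearby genes ELAC1, MEX3C and ME2 had log2 fold changes of 0.61, 0.529 and -0.1. A smaller gain around SMAD4 was not tested. Reads of the 2 overlapping genes counted as SMAD4 stay open: those genes held 0.444 CPM where SMAD4 gained 44.4 CPM, but reads counted as SMAD4 would be missing from them. An exchange of the group labels stays open and cannot be told apart from a real rise: the TGF-beta and BMP targets leaned upward with a raw p of 0.245 (camera, estimated correlation), which decides nothing. If the labels were exchanged, the direction of every comparison here would turn over, and a rise in SMAD4 for another biological reason was not tested.

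Control replicate 4 lay apart from the other controls. RNA of the libraries labelled knockdown mixed into it is argued against, since over 37 genes high in those libraries the implied share was 0.00108 and over 11 genes high in the controls it was -0.588. A trend with gene length or GC content is argued against as the whole cause, since 82% as many genes stayed at least 2-fold apart after its removal, but it may be part of it: that share counts many low-count genes, and among genes of at least 8 CPM the number went from 1519 to 885, or 58.3%, against 19 to 159 in the other controls, and the difference followed length with a Spearman correlation of -0.293 across genes. RNA of another cell type stays open, with the largest of 5 marker medians, that of hepatocytes, at 0.539, between the bounds set for and against it. No biological explanation was tested, since the labels give control replicate 4 no condition of its own.

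The last pattern was 132 protein-coding genes at least 8-fold apart between the groups and under 1 CPM in the lower group. Of these, 83 were higher in the libraries labelled knockdown and 49 in the controls. No minimum level was set for the higher group, so some may be low in both groups. Lost or gained chromosome segments would set neighbours together, and of the 69 that are autosomal and at 1 CPM or more in a group, 0% lay in runs of 3 or more neighbours, although 2 neighbouring pairs were found where 1000 shuffles gave 0.197 on average (one-sided permutation test over positions, p = 0.021). The run test covers only segments whose genes differ at least 8-fold, so it decides nothing about gains or losses that shift genes less. Among genes of at least 8 CPM, the log2 fold changes of neighbours had a rank correlation of 0.123, against at most 0.0334 in 1000 shuffles. Shuffling removes every likeness of neighbours, also that from overlapping reads, so this decides nothing about segments. A difference in depth is argued against by a ratio of mean library totals of 1.05. RNA of another cell type stays open: the largest of 5 marker medians was 0.785, that of fibroblasts, a list that rose at the preset correlation (camera, adjusted p = 0.00484) but not at an estimated one (0.225) or in 8 limma settings, and leukocyte and adipocyte markers went both ways. A biological difference between the labelled groups also stays open, as untested, and segments for the remaining genes were not tested.

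The counts of changed genes were set against other splits of the libraries, which cannot exclude chance. Every other split mixes the labelled groups, which widens the spread within each side and leaves few calls. The replicates may also be technical. Of the 35 splits of the 8 libraries into 4 and 4, only the real split, 1 of 35, gave as many: 2912 higher, 2698 lower, 1051 higher and 989 lower at least 2-fold, against at most 1 gene in any other split.

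In a group of 4 libraries, 1 library can lie far from the rest, and 20 of 198 groups examined had a gap over 0.83 of the whole range, where chance gives about 1 in 20. Control replicate 4 was that library in 11. The gap was 0.885 of the range for MYD88, 0.831 for B2M, 0.838 for PSAT1, 0.835 for BMPR2, 0.925 for VIM, 0.889 for ESRP2, 0.898 for AURKA, 0.86 for GPR50 and 0.926 for SPINT2, and it was 0.87 for the number of genes with a count and 0.897 for the share of ribosomal protein genes. Among the libraries labelled knockdown, replicate 2 stood apart for CCL5 (0.846), CXCL16 (0.855) and SNAI2 (0.876), replicate 3 for VLDLR (0.874) and COL5A1 (0.833), replicate 4 for SMAD2 (0.856) and MDM2 (0.916), and replicate 1 for COL3A1 (0.866) and RND2 (0.929).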

How the results depend on the processing

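The separate report of values without control replicate 4, total-count scaling, robust edgeR, the FPKM filter of 1, the Gene Ontology test without control replicate 4, and the length and GC correction were chosen after seeing the data. No gene called with all libraries was called in the opposite direction under any of 25 settings. In the 24 settings that tested them (the FPKM filter of 5 removed both), SMAD4 stayed called and higher, with log2 fold changes of 1.01 to 1.5 (1.40 to 1.47 leaving out 1 library). STING1 ranged from 0.08 to 0.43 (0.28 to 0.38 leaving out 1 library) and from adjusted p = 0.0412 to 0.495. It passed with limma on TPM (0.4346, adjusted p = 0.0432), where the median of all genes also rose, to 0.159 from 0.0635 with limma on log2(FPKM + 0.5). STING1 passed as well with limma on FPKM without a variance trend (0.2639, adjusted p = 0.0412), the cause of which was not tested. Leaving out 1 library at a time gave 1880 to 4634 higher genes and 1781 to 4321 lower genes. The higher count moved by over 1.5 times without replicate 1, 2 or 4 labelled knockdown (1900, 1890 and 1880), the lower count without replicate 3 (1781), and both without control replicate 4 (4634 and 4321).

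A stricter FPKM filter of 5 gave 1266 higher and 1435 lower genes, 144 and 204 at least 2-fold, and one of 1 gave 412 and 525 at least 2-fold, with fewer genes tested. Counts at least 2-fold, higher and lower, were 317 and 280 with limma on log2(FPKM + 0.5), 486 and 395 with a pseudocount of 0.1, 197 and 215 with 1, 258 and 337 with median centring, 249 and 362 with quantile normalization, 318 and 280 without a variance trend and 315 and 280 with robust eBayes. A larger pseudocount shrinks the fold of low genes by construction. TPM gave 600 and 313 at least 2-fold, and 1538 lower genes in all. The Gene Ontology terms numbered 86 against all genes tested and 20 for genes at least 2-fold changed. After length and GC trends were removed, limma on log2 CPM gave 2954 higher and 3787 lower, against 3119 and 2616 before, with 5149 genes shared. The causes of the other moves were not tested.

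The replicate number as a block gave 2189 higher and 1900 lower genes. The correlations of deviations for equal numbers were -0.0768, 0.0678, -0.0567 and 0.0527, so the numbers do not pair the libraries, and not every library correlated best with its own number.

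The sign of the list test turned only in lists that were not called. For epithelial junction and keratin genes the list medians, which need not share the sign of the test, were then 0.128, 0.144 and 0.104 with limma on FPKM at pseudocounts of 0.5, 0.1 and 1, 0.128 without trend and 0.128 with robust eBayes, 0.0557 and 0.0355 with FPKM filters of 5 and 1, 0.233 with TPM, 0.0702 with median centring, 0.0622 with quantile normalization and 0.072 without replicate 1 labelled knockdown (-0.109 to 0.107 leaving out each library). For NRF2 targets they were -0.0996 and -0.243 with those filters and -0.154 and -0.135 without replicates 2 and 3 labelled knockdown (-0.337 to -0.135 leaving out each library), for leukocyte markers -0.727 with no filter and -0.735 with DESeq2, for WNT targets 0.108 with the FPKM filter of 5, and for G1/S genes 0.0926 with quantile normalization. Calls were gained 11 times for lists and 11 times for single genes named in the text or by the rule. The call on fibroblast markers was lost in 8 limma settings, and that on p53 targets with the FPKM filter of 1, TPM and no variance trend. Genes of very low level could not be tested, such as CGAS, which had at most 16 counts and 0.237 CPM in any library.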

Other observations

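The genes below were chosen only after their values were seen. The single heat-shock genes HSPH1, HSPA8, HSP90AA1, HSPD1 and DNAJB1 had log2 fold changes of -1.67, -1.34, -1.05, -0.83 and -0.61 in the libraries labelled knockdown against control, and heat-shock genes were not tested as a group. NEFL fell by 2.40 on the log2 scale. TLR3, a receptor for double-stranded RNA, and DHX58, a relative of RIG-I, rose by 1.92 and 1.44, and ISG15 by 2.55.

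Without control replicate 4, 6 Gene Ontology terms passed among the genes that rose, led by the cytosolic ribosome with 39 of 70 genes, and 72 among those that fell, led by the mitochondrial inner membrane with 181 of 421. Cytoplasmic translation genes lay higher in control replicate 4 than in the other controls by a median log2 difference of 1.03, and 4 of 82 rose with that library and 42 without it. Across 10195 genes of at least 8 CPM, the log2 fold changes of neighbouring genes had a rank correlation of 0.123, where 1000 shuffles reached at most 0.0334. Genes are not independent replicates, and shuffling removes the likeness of neighbours whatever its source. By chromosome, the median log2 fold change was lowest on chromosome 21 at -0.31 over 100 genes and on chromosome 17 at -0.16 over 651 genes. KRT19, a bile duct keratin, was at 0.986 ± 0.644 and 0.814 ± 0.492 CPM, and KRT8 at 94.4 ± 2.38 and 92.1 ± 14.3 CPM, in the libraries labelled knockdown and control (SD, n = 4 each).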
